A study of Mus musculus with 24 samples.

How the data were processed

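RNA was measured by sequencing in neutrophil preparations from the blood and liver of NOD.c3c4 mice. Per the labels, RNA was purified with the RNeasy Mini kit and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name Bowtie2 2.2.5, STAR 2.5.3a, Partek and DESeq2 with the mouse build mm10, without saying which step each performed. The counting tool, the gene annotation and any filter on genes are not stated.

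The deposited table of the antibody libraries holds raw counts per gene for 15 libraries and 22505 rows, all values whole. The deposited table of the blood and liver libraries holds expected counts per gene for 9 libraries and 18474 rows, with 44.4% of values not whole. These estimated counts were rounded to whole numbers. Neither table had been scaled between libraries. In the 9-library table, 15 gene symbols had been turned into dates. These rows held 0.079% of the counts and were kept in the library totals but not used for named genes. The antibody table had 5 symbols on more than 1 row, and its smallest row sum was 11 counts. Of the symbols, 17943 and 22261 matched GENCODE M21, and 93.2% of the matched genes of the 9-library table had the same position in it. Every column of per-sample values was mapped to a sample, and no libraries were identical.

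The 9-library and antibody tables were analysed separately. Genes were kept by filterByExpr with the groups (16719 and 16812 genes), scaled by TMM and tested by the edgeR quasi-likelihood F test with robust dispersion, group as the only term and all libraries of the table in the fit. Adjusted p-values are Benjamini-Hochberg over the tested genes of a comparison, with 0.05 as the threshold. The standard error of a log2 fold change was taken as its size divided by the square root of F. The interaction was the treatment effect in liver minus that in blood. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Levels are CPM (counts scaled to library size, after TMM), as mean ± SD over libraries. No fold is given for a gene with 3 counts or fewer over a group. This limit and the bounds for genes at 0 cover counting error only, whereas the 95% intervals come from the standard errors of the fit, which include the spread between libraries.

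Gene lists were fixed before the data were examined: 22 of pathways and neutrophil genes, 13 of markers of other cell types and 1 of sex-linked genes. Each list with at least 3 tested members was tested with limma camera on log2 CPM (prior count 2, preset correlation 0.01), and p-values were adjusted over all lists and comparisons of a table (175 and 180 tests). Camera was repeated with the correlation between genes estimated from the data. Of the camera calls, 78 in the 9-library table and 68 in the antibody table passed with the preset correlation. With the estimated correlation 0 and 0 passed, where 10 and 6 tests had an unadjusted p under 0.05 and the smallest adjusted p was 0.562 and 0.829. The median estimated correlation was 0.392 and 0.395. Counts of list members are those past the threshold adjusted over all genes. The count adjusted over the list alone stands beside it where it differs, and was otherwise the same. Some lists share genes, such as Mmp9 and Itgam in both the identity and gelatinase granule lists, and macrophages also express several of the neutrophil identity genes.

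The rule for named genes was fixed before the data were examined. It takes, per direction, the 8 largest folds of a 9-library comparison and the 5 largest of an antibody comparison among genes past the threshold with at least 10 CPM in the higher group and no overlap between the groups (not asked for the interaction). Symbols of unnamed gene models and immunoglobulin or T cell receptor segments are passed over. It adds up to 4 members of each list with the smallest adjusted p, and 11 fixed genes (Camp, Ltf, Mpo, Elane, S100a8, Cxcr2, Cxcr4, Il10, Arg1, Cd274 and Il1b) whatever their values. The genes in the text are a selection from those the rule gave, made after their values were seen.

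The genes that separated treated from untreated liver were also tested as an up and a down set in the antibody comparisons, with p-values adjusted over these 10 tests. No library is shared between the tables.

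Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter on low counts, a filter of 5 CPM in 2 libraries, a replicate block by title or library-name number, a fit of only the groups compared, an absolute log2 fold change of at least 1, and leaving out each library. A fit that leaves 1 library in a group assumes that it varies like the other groups. After seeing the data, 4 were added: fits without untreated liver, fits without the anti-GCF libraries, a signature from treated liver against treated blood, and a direct comparison of the anti-TGFb and anti-IL10 libraries.

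The fit was tested on simulated data with the depths, spreads and group sizes of the libraries and 100 planted genes at each size of effect. At a log2 fold change of 1 it recovered 36% of planted genes in treated against untreated liver, 68% in anti-IL21R and 45% in anti-IL10 against isotype. At a log2 fold change of 2 it recovered 85%, 97% and 97%. False calls made up 7.8%, 2.3% and 5.5% of all calls. A list planted at a log2 fold change of 1 was found in all 3 comparisons by camera with the preset correlation, while 0 of 34, 0 of 35 and 1 of 35 other lists were called. The simulated genes varied independently, unlike those of the libraries (median estimated correlation 0.392 and 0.395). These counts therefore cannot show how the preset correlation performs on the real lists.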

Results

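The study profiled neutrophils of the liver and blood of mice with and without nanoparticle therapy. RNA came from neutrophil preparations of NOD.c3c4 mice, a strain that develops autoimmune bile duct disease and serves as a model of primary biliary cholangitis. Treated mice had received 10 intravenous doses of nanoparticles coated with PDC166, which the series describes as peptide-MHC coated particles. The 9-library table holds blood neutrophils of untreated (n = 3) and treated mice (n = 2) and liver neutrophils of untreated (n = 2) and treated mice (n = 2). The antibody table holds liver neutrophils of treated mice given an isotype control (n = 3) or an antibody labelled anti-GCF (n = 3), anti-IL21R (n = 3), anti-TGFb (n = 2), anti-IL35 (n = 2) or anti-IL10 (n = 2). Libraries held 34.7 to 46.4 M counts in the 9-library table and 23.6 to 47.5 M in the antibody table. S100a9, a calprotectin subunit abundant in neutrophils, took up to 9.95% of a library. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples. Treated and untreated libraries also fall into separate ranges of library numbers, and a batch along that line cannot be told apart from treatment.

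Treated and untreated liver were compared to ask what the therapy changes in liver neutrophils. Treated liver libraries held more RNA of neutrophil granule proteins, of the NADPH oxidase and of the cell cycle, and far less RNA of hepatocytes. Camp, the gene of the antimicrobial cathelicidin (mm10, chromosome 9, 109847379 to 109849617), stood at 7706 ± 662 CPM (SD, n = 2) in treated and 549 ± 220 CPM (n = 2) in untreated liver, a log2 fold change of 3.81 ± 0.67 (SE, adjusted p = 0.00084). Ltf, the gene of the specific granule protein lactoferrin (chromosome 9, 111019271 to 111042767), stood at 20090 ± 1240 against 729 ± 276 CPM, a log2 fold change of 4.78 ± 0.67 (adjusted p = 0.000209). S100a8, the other calprotectin subunit (chromosome 3, 90668978 to 90670035), stood at 47630 ± 1510 against 7246 ± 1020 CPM, a log2 fold change of 2.72 ± 0.43 (adjusted p = 0.000423). Hepatocyte markers summed to 17336 ± 3720 CPM in untreated liver (n = 2), 279 ± 17.6 in treated liver (n = 2), 461 ± 97.1 in untreated blood (n = 3) and 325 ± 14.1 in treated blood (n = 2).

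**Figure D1:**
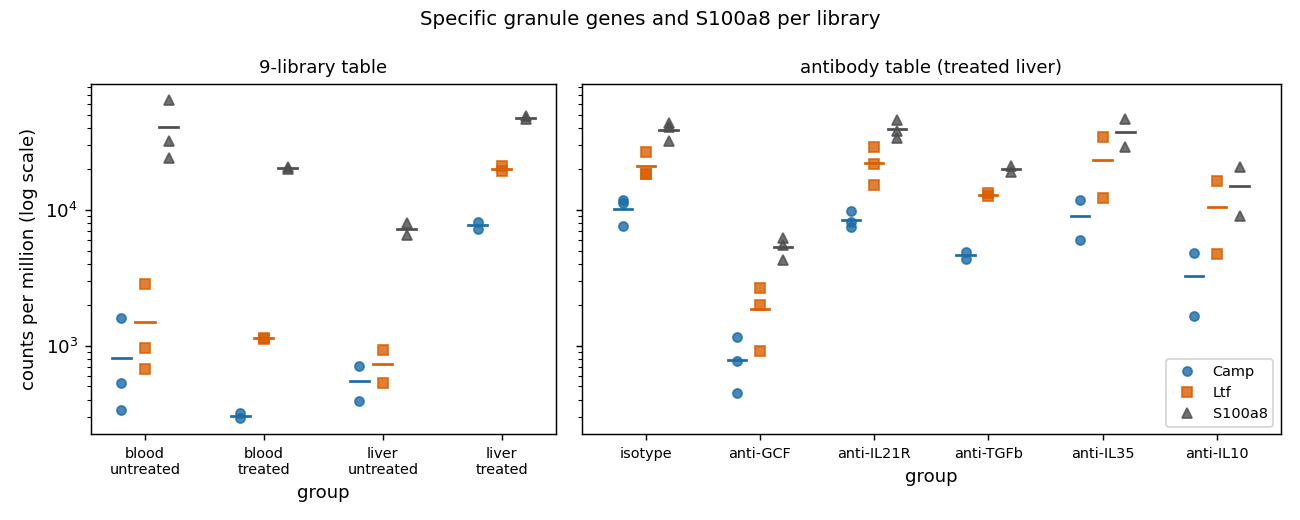
Level of Camp, Ltf and S100a8 in each library (points; CPM, log axis) by group, with the group mean as a bar. In the 9-library table treated liver stands highest for Camp and Ltf (means of 7706 and 20090 CPM), and in the antibody table anti-GCF stands lowest (means of 789 and 1856 CPM).

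Granule genes of treated liver rose as families. Of 14 specific granule genes 13 rose and 1 fell (median log2 fold change 3.38, camera adjusted p = 7.24e-05), of 13 gelatinase granule and secretory vesicle genes 12 rose and 1 fell (2.06, 0.000338), and of 10 azurophil granule genes 8 rose and 1 fell (2.65, 0.00632). The adjusted p with an estimated correlation were 0.562, 0.594 and 0.562. Olfm4, a marker of a subset of neutrophils, rose by log2 4.42 ± 0.60 (SE), and Chil3, a chitinase-like secreted protein, by 3.51 ± 0.33. Mpo (myeloperoxidase) and Elane (neutrophil elastase), made in granulocyte precursors, rose from 3.66 ± 0.82 to 43.5 ± 20.9 CPM and from 4.86 ± 0.84 to 42.4 ± 18.3 CPM (n = 2 each). Among 20 neutrophil identity genes 16 rose and 0 fell in edgeR (median 1.79, camera adjusted p = 5.98e-05, and adjusted p = 0.562 with an estimated correlation). Mmp9, a gelatinase, rose by 2.06 ± 0.27, Itgam, the CD11b integrin chain, by 2.25 ± 0.23, and Cxcr2, the receptor of neutrophil-attracting chemokines, by 0.79 ± 0.19. All 7 NADPH oxidase genes rose (median 1.94, camera adjusted p = 0.000981, and 0.562 as the adjusted p with an estimated correlation), among them Cybb by 2.92 ± 0.28, Ncf1 by 2.95 ± 0.35 and the proton channel gene Hvcn1 by 3.83 ± 0.27. Beside these groups hepatocyte markers went the other way, all 17 lower (median −6.84). B and plasma cell markers summed to 692 ± 71.9 CPM in treated and 3498 ± 99.8 CPM in untreated liver. The medians of the gelatinase granule (2.06) and NADPH oxidase genes (1.94) were near that of the identity genes (1.79). Less RNA of other cells as a cause was tested only for the specific granule genes, and for the other lists it stays open.

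Proliferation genes and early response genes were also higher in treated liver. Of 30 cell cycle genes 27 rose and 1 fell (median 3.26, camera adjusted p = 3.17e-08, and adjusted p = 0.562 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose from 2.46 ± 0.66 to 50.2 ± 15 CPM, and Ccna2, the cyclin of DNA synthesis, from 2.05 ± 1.14 to 27.3 ± 7.54 CPM (n = 2 each). Erythroid markers rose with them, 8 of 10 higher and 0 lower (8 and 1 adjusted over the list alone, median 6.68, or 6.67 with genes at 0 set to their bound, camera adjusted p = 0.00745, and adjusted p = 0.562 with an estimated correlation). Of 19 immediate-early genes 12 rose and 1 fell (15 and 2 adjusted over the list alone, median 1.47, camera adjusted p = 0.00111, and adjusted p = 0.594 with an estimated correlation). Jun, an AP-1 transcription factor, rose by 3.54 ± 0.25 and Klf2, a factor of cell quiescence, by 1.84 ± 0.22. Tnf and Nfkbiz, of the NF-kB response, rose by 3.76 ± 0.29 and 3.40 ± 0.23, while that list as a whole did not pass (camera adjusted p = 0.0702).

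Lower in treated liver were genes of protein synthesis, respiration and liver metabolism. Of 75 oxidative phosphorylation genes 69 fell and 1 rose (median −1.91, camera adjusted p = 1.96e-11), and of 86 cytosolic ribosomal protein genes 70 fell and 4 rose (71 and 4 adjusted over the list alone, median −1.45, 1.48e-07). Under an estimated correlation the adjusted p were 0.562 and 0.626. All 17 hepatocyte markers fell (median −6.84, camera adjusted p = 1.22e-06, and adjusted p = 0.562 with an estimated correlation). Arg1, the arginase of hepatocytes and of some myeloid cells, stood at 2.64 ± 0.74 against 1033 ± 295 CPM, and Cyp2e1, a hepatocyte cytochrome, at 2.09 ± 0.12 against 914 ± 105 CPM (n = 2 each). Hspd1, a mitochondrial chaperone with processed pseudogenes, fell by 4.96 on the log2 scale (SE 0.22), and Sod2, the mitochondrial superoxide dismutase, fell by 3.70 (SE 0.23). T and NK cell markers fell as well, 10 of 15 lower and 1 higher (11 and 1 adjusted over the list alone, median −2.90, or −2.75 with genes at 0 set to their bound, camera adjusted p = 0.045, and adjusted p = 0.681 with an estimated correlation). The member that rose, Cd3d, a chain of the T cell receptor complex, stood at 251 ± 15.9 against 46.7 ± 12.3 CPM and made up most of the sum of this list in treated liver, which was higher than in untreated liver (263 ± 15 against 136 ± 51.6 CPM), opposite to the median. Cd274, the PD-L1 gene, stood at 28.5 ± 5.49 against 25.0 ± 2.82 CPM (adjusted p = 0.762), and Cxcr4, a marrow-homing receptor, at 557 ± 78.8 against 318 ± 129 CPM (adjusted p = 0.243). In all, 4649 genes rose and 6071 fell of 16719 tested. Scaling moved the median of all genes by 0.11 (RLE and DESeq2) and 0.27 (upper-quartile), and with the last 5437 rose and 5321 fell, so directions of small changes here depend on it.

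Treated and untreated blood were compared to ask whether the therapy acts on circulating neutrophils. Treated blood held more RNA of cell cycle genes, of some interferon response genes, and of T, NK and other blood cells, and less of neutrophil identity genes. Top2a stood at 11.8 ± 2.28 CPM (n = 2) against 0.40 ± 0.08 CPM (SD, n = 3), a log2 fold change of 4.89 ± 0.31 (adjusted p = 0.000147). Mki67, the Ki-67 proliferation antigen, rose by 4.53 ± 0.58. Of 30 cell cycle genes 28 rose (29 adjusted over the list alone) and 0 fell in edgeR (median 2.63, camera adjusted p = 1.13e-11, and adjusted p = 0.562 with an estimated correlation). Erythroid markers moved with them, 7 of 10 higher (10 adjusted over the list alone, median 3.91, or 3.77 with genes at 0 set to their bound, camera adjusted p = 0.00765, and adjusted p = 0.562 with an estimated correlation). Mpo rose by 3.42 ± 0.48 and Elane by 2.85 ± 0.38, from levels under 1 CPM.

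Saa3, an acute-phase protein made by myeloid cells, rose from 10.4 ± 3.70 (n = 3) to 509 ± 48.4 CPM (n = 2) in blood, and Chil3 from 770 ± 249 to 3472 ± 237 CPM. Nos2, the inducible nitric oxide synthase, rose by 3.83 ± 0.73, Gbp6, a GTPase induced by interferon-gamma, by 4.47 ± 0.50, and Iigp1, another such GTPase, by 3.58 ± 0.36. Of 36 interferon response genes 10 rose and 1 fell (median 0.60, camera adjusted p = 0.0184, and adjusted p = 0.80 with an estimated correlation), among them Oas2 by 2.48 ± 0.19 and Slfn4 by 2.03 ± 0.20. Their summed level overlapped, at 5870, 3542 and 2451 CPM in untreated blood replicates 1, 2 and 3 and 5295 and 5512 CPM in treated blood. T and NK cell markers rose beside them, 7 of 15 higher and 1 lower (10 and 2 adjusted over the list alone, median 1.81, camera adjusted p = 0.0108, and adjusted p = 0.626 with an estimated correlation). Gzma, a granzyme of killer lymphocytes, stood at 237 ± 11.6 against 15.4 ± 2.68 CPM. Kupffer cell and macrophage markers also rose, 9 of 13 higher and 1 lower (median 4.03, or 3.91 with genes at 0 set to their bound, camera adjusted p = 0.000533), as did all 9 platelet markers (median 1.87, 0.00072). Each adjusted p with an estimated correlation was 0.562. The summed level of the macrophage markers went the other way, 1100 ± 47.5 (n = 2) against 1550 ± 243 CPM (n = 3), as Slc40a1, the iron exporter ferroportin, stood at 862 ± 33.1 against 1380 ± 191 CPM. C1qb, a complement gene of macrophages, rose by 4.22 ± 0.37 and Pf4, platelet factor, by 1.87 ± 0.23.

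Lower in treated blood were 8 of 20 neutrophil identity genes with 1 higher (median −0.84, camera adjusted p = 0.00171, and adjusted p = 0.607 with an estimated correlation). Untreated replicate 3 stood apart, with summed levels of 121969, 147416 and 287096 CPM in untreated replicates 1, 2 and 3 against 95438 and 92270 CPM in treated blood. G0s2, a lipolysis inhibitor, fell by 1.91 on the log2 scale (SE 0.28), and Osm, the cytokine oncostatin M, fell by 2.56 (SE 0.34). Ribosomal protein genes (39 of 86 lower and 0 higher in edgeR, 46 and 1 adjusted over the list alone, median −0.60, camera adjusted p = 6.77e-09) and oxidative phosphorylation genes (47 of 75 lower, 53 adjusted over the list alone, median −0.69, 2.88e-12) fell. Adjusted p with an estimated correlation were 0.594 and 0.562. Hepatocyte markers fell too, 11 of 17 (median −3.29, camera adjusted p = 1.68e-07, and adjusted p = 0.562 with an estimated correlation), from low levels such as 12.5 ± 3.65 CPM of Alb (albumin, n = 3). The specific granule genes did not pass as a group (1 higher and 3 lower of 14, camera adjusted p = 0.402). Camp stood at 305 ± 20.5 against 817 ± 672 CPM (adjusted p = 0.0847) and Ltf at 1132 ± 19.6 against 1488 ± 1170 CPM (adjusted p = 0.593). In all, 2917 genes rose and 2703 fell. The count of 5620 dropped to 3442 with a log2 fold change of at least 1, to 2155 without treated blood replicate 2 and to 1723 without replicate 3.

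Liver and blood of treated mice were compared to ask what sets liver neutrophils apart under therapy. Treated liver had higher levels of specific granule, azurophil granule and cell cycle genes and lower levels of interferon response genes and cytokine receptors than treated blood. Camp was higher by log2 4.66 ± 0.70 (SE, adjusted p = 0.00183), from 305 ± 20.5 CPM in blood (n = 2), and Ltf by 4.15 ± 0.65 (adjusted p = 0.00235), while S100a8 did not pass (log2 1.24 ± 0.41, adjusted p = 0.0581). Of 14 specific granule genes 9 were higher (13 adjusted over the list alone) and 0 lower in edgeR (median 1.97, camera adjusted p = 3.4e-06, and adjusted p = 0.562 with an estimated correlation). Azurophil granule genes were 7 higher and 2 lower of 10 (8 and 2 adjusted over the list alone, median 1.85, camera adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation), with Elane higher by 3.60 ± 0.38. The gelatinase granule and secretory vesicle genes did not pass (1 higher and 1 lower of 13, median 0.46, camera adjusted p = 0.207). All 30 cell cycle genes were higher (median 2.31, camera adjusted p = 2.32e-13, and adjusted p = 0.562 with an estimated correlation), among them Birc5 (survivin) by 2.69 ± 0.35 and Ccnb1, a mitotic cyclin, by 2.55 ± 0.34. Erythroid markers did not pass beside them (3 of 10 higher, 5 adjusted over the list alone, median 1.5, camera adjusted p = 0.0718). Of 19 immediate-early genes 8 were higher (median 0.76, camera adjusted p = 0.00142, and adjusted p = 0.594 with an estimated correlation). Osm was higher by 2.92 ± 0.36 and Tnf by 2.83 ± 0.28, whereas Il1b, the other main inflammatory cytokine gene followed here, was lower, at 540 ± 0.09 against 2533 ± 84.6 CPM (n = 2 each).

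Interferon response genes were lower in treated liver than in treated blood in 19 of 36 (24 adjusted over the list alone, median −1.44, camera adjusted p = 1.53e-07, and adjusted p = 0.594 with an estimated correlation). Oasl2, an antiviral gene, was lower by a log2 fold change of −2.22 ± 0.33. Receptor genes of a list named for the blocked cytokines were lower in 9 of 11 (11 adjusted over the list alone, median −1.61, camera adjusted p = 3.4e-06, and adjusted p = 0.562 with an estimated correlation), among them Il10ra (−2.48 ± 0.29) and Il27ra (−4.43 ± 0.56). This list includes the receptor gene Csf3r, although the labels do not say that GCF is its ligand. Socs3, a feedback inhibitor of cytokine signalling, stood at 102 ± 4.45 against 552 ± 27.4 CPM, and Nos2 at 0.79 ± 0.30 against 127 ± 0.62 CPM. Other cells differed beside these groups: all 9 platelet markers (median −9.58, camera adjusted p = 1.28e-12) and 12 of 15 T and NK markers (13 adjusted over the list alone, with 1 higher in both, median −4.97, 1.46e-07) were lower in liver. Kupffer cell and macrophage markers were lower in 9 of 13 (10 adjusted over the list alone, median −3.03, or −2.93 with genes at 0 set to their bound, camera adjusted p = 9.77e-06), and hepatocyte markers higher in 15 of 17 (16 with 1 lower adjusted over the list alone, median 5.28, 2e-11). Under an estimated correlation each adjusted p was 0.562. Summed levels of the hepatocyte markers did not differ in that direction (279 ± 17.6 against 325 ± 14.1 CPM), since Trf, transferrin, stood at 199 ± 5.38 against 322 ± 11.2 CPM. Cxcr2 was lower by log2 −0.81 ± 0.19 (adjusted p = 0.0146) and Cd274 by −1.76 ± 0.52 (adjusted p = 0.0402), but leaving out any of the 4 libraries ended both calls, with values from −0.87 to −0.75 and from −1.97 to −1.57. In all, 1624 genes were higher and 1944 lower in liver, a balance that turned with RLE scaling (1860 and 1782) and DESeq2 (2391 and 2175). The total of 3568 was 8188 in a fit of these groups alone, and 1611, 1496, 1467 and 1469 without liver replicate 1, liver replicate 2, blood replicate 2 and blood replicate 3.

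**Figure D2:**
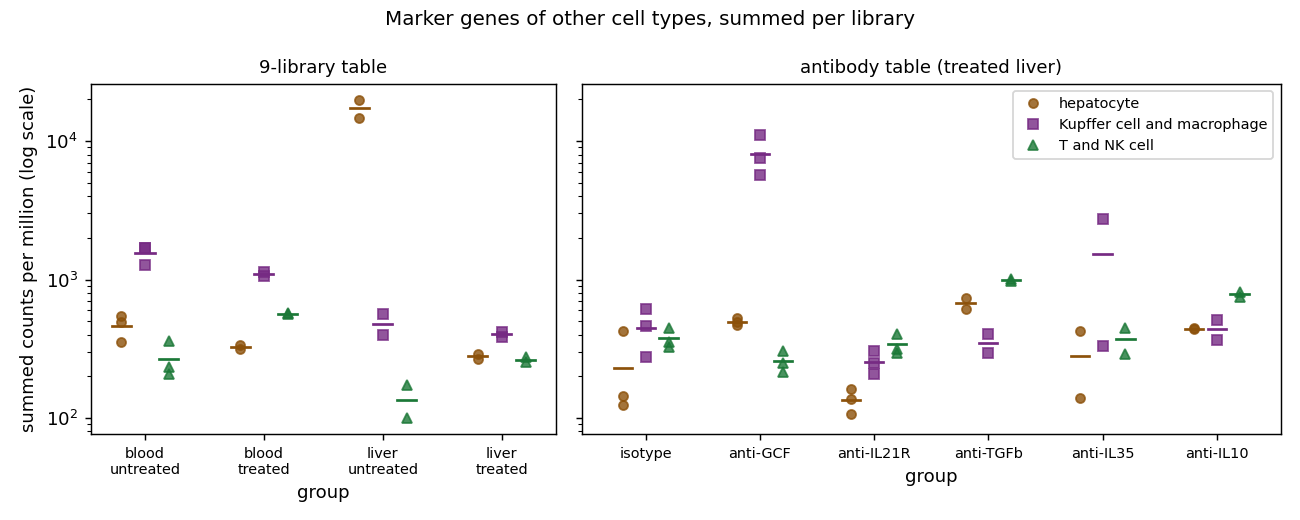
Summed level of hepatocyte, of Kupffer cell and macrophage, and of T and NK cell markers in each library (points; CPM, log axis) by group. Hepatocyte markers stand highest in untreated liver (14705 and 19966 CPM), macrophage markers in anti-GCF (5733 to 11080 CPM), and T and NK markers in anti-TGFb (969 and 1016 CPM).

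Liver and blood of untreated mice give the background against which the therapy acts. Neutrophil identity genes were lower in untreated liver than in untreated blood, and liver genes were far higher. All 20 identity genes were lower (median −2.12, camera adjusted p = 2.84e-07), with S100a8 at 7246 ± 1020 (n = 2) against 40290 ± 21500 CPM (n = 3) and Cxcr2 at 1357 ± 150 against 5330 ± 565 CPM. All 17 hepatocyte markers were higher (median 8.70, 1.46e-07), and oxidative phosphorylation genes were higher in 63 of 75 and lower in 4 (64 and 4 adjusted over the list alone, median 1.43, 2.88e-08). The adjusted p with an estimated correlation were 0.562, 0.562 and 0.594. Specific granule genes were lower in 9 of 14 and higher in 1 (median −1.32, camera adjusted p = 0.017, and adjusted p = 0.667 with an estimated correlation), while Camp did not pass (log2 −0.57 ± 0.56, adjusted p = 0.39). Cell cycle genes were higher in 24 of 30 (25 adjusted over the list alone, median 2.05, camera adjusted p = 0.000209, and adjusted p = 0.562 with an estimated correlation), with Tk1, thymidine kinase, higher by 5.52 ± 0.43. Iigp1 was higher in liver by 7.47 ± 0.40, and Socs3 was lower (−2.59 ± 0.17). In all, 5953 genes were higher and 4797 lower in liver. Upper-quartile scaling moved the median of all genes by −0.23 and gave 5357 higher and 5551 lower, and a filter of 5 CPM in 2 libraries gave 4328 and 4419.

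The interaction asks whether the therapy acts on liver neutrophils as it does on blood neutrophils. Treatment effects differed for specific granule, identity, NADPH oxidase and immediate-early genes, which had higher effects in liver, and for macrophage, T and NK cell and hepatocyte markers, which went the other way. The liver effect on Camp exceeded the blood effect by log2 5.23 ± 0.88 (SE, adjusted p = 0.000978), and that on Ltf by 5.18 ± 0.84 (adjusted p = 0.000805). Of 14 specific granule genes 12 had a higher effect in liver (median 3.37, camera adjusted p = 4.64e-05), of 20 identity genes 18 (2.61, 3.94e-07), of 7 NADPH oxidase genes 7 (2.52, 0.000145), and of 19 immediate-early genes 14, with 1 lower (2.11, 0.000145). Each adjusted p with an estimated correlation was 0.562. Cell cycle genes did not pass, with 3 higher and 2 lower of 30 (1 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.247), nor did the azurophil granule genes (4 higher and 2 lower of 10, median 0.63, camera adjusted p = 0.162), Mpo (0.15 ± 0.70, adjusted p = 0.87) or Elane (0.28 ± 0.54, adjusted p = 0.688). Osm (6.31 ± 0.51), Has2, a hyaluronan synthase (6.75 ± 0.73), and Fosl1, an AP-1 factor (7.25 ± 1.31), had some of the largest positive differences, and Iigp1 (−8.17 ± 0.55), C1qc (−7.68 ± 0.55) and Gzma (−7.06 ± 0.40) some of the largest negative ones. Beside these groups the macrophage markers had a lower effect in liver in 9 of 13 (median −7.15, camera adjusted p = 0.00765, and adjusted p = 0.562 with an estimated correlation) and the T and NK markers in 9 of 15 with 1 higher (11 and 1 adjusted over the list alone, median −4.47, camera adjusted p = 0.011, and adjusted p = 0.626 with an estimated correlation). The hepatocyte markers had a lower effect in 10 of 17 (11 adjusted over the list alone, median −3.35, camera adjusted p = 0.000963, and adjusted p = 0.578 with an estimated correlation). In all, 3897 genes had a positive and 5246 a negative difference. The large amount of hepatocyte RNA in untreated liver enters the liver effect, so these differences also hold a difference in cell content. A far smaller amount enters the blood effect, with Alb at 9.08 to 16.3 CPM in untreated and 0.718 and 0.082 CPM in treated blood. Scaling moved the median of all genes by 0.13 (RLE and DESeq2) and 0.21 (upper-quartile).

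The antibody libraries ask how blocking single factors alters the neutrophils of treated liver. The labels do not say what GCF stands for, so the target of that antibody is not known here. Under anti-GCF, neutrophil and granule genes were lower than under isotype and macrophage, monocyte, dendritic cell and antigen presentation genes were higher. Camp stood at 789 ± 356 CPM (SD, n = 3) against 10180 ± 2320 CPM (n = 3), a log2 fold change of −3.69 ± 0.45 (SE, adjusted p = 2e-05), and Ltf at 1856 ± 885 against 21030 ± 4810 CPM (−3.50 ± 0.55, adjusted p = 0.00014). All 14 specific granule genes fell (median −2.89, camera adjusted p = 1.92e-06), as did 9 of 10 azurophil genes with 1 higher (−2.64, 0.000865), 17 of 20 identity genes (−2.10, 6.54e-08), 12 of 13 gelatinase granule genes (−1.71, 2.83e-05), 16 of 18 glycolysis genes (−1.26, 2.83e-05) and all 7 NADPH oxidase genes (−1.18, 0.00311). Under an estimated correlation each adjusted p was 0.829. The summed level of the azurophil genes differed little (762.1 ± 139.1 against 799.3 ± 98.7 CPM), as Ctsc, cathepsin C, was higher (619 ± 166 against 97.6 ± 17.9 CPM). Elane fell by 4.71 on the log2 scale (SE 0.69), S100a8 fell by 2.86 (SE 0.34), and Il1r2, a decoy receptor of interleukin-1, fell by 3.77 (SE 0.29). Cxcr2 stood at 988 ± 17.9 against 1012 ± 181 CPM (adjusted p = 0.914). Slc2a3, the neuronal-type glucose transporter also used by leukocytes, fell by 1.92 (SE 0.19), and Thbs1, thrombospondin, fell by 5.91 (SE 0.77). Cell cycle genes fell in 20 of 30 (median −0.77, camera adjusted p = 5.37e-05, and adjusted p = 0.829 with an estimated correlation). Erythroid markers fell beside them in 5 of 10 with 1 higher (median −2.75, camera adjusted p = 0.0327, and adjusted p = 0.829 with an estimated correlation), with sums that overlapped (1171.5 ± 722.4 against 1175.3 ± 922.4 CPM).

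Myeloid genes of other cells rose under anti-GCF. All 13 Kupffer cell and macrophage markers rose (median 4.47, camera adjusted p = 0.00031), with their sum at 8105 ± 2724 against 449 ± 169 CPM (SD, n = 3 each). Monocyte markers rose in 9 of 10 (median 3.08, 0.00045), dendritic cell markers in 8 of 10 (2.77, 0.000759) and MHC class II genes in 12 of 13 with 1 lower (2.49, 9.27e-05). Each adjusted p with an estimated correlation was 0.829. B and plasma cell markers, of cells that also express MHC class II, did not pass as a list (7 of 12 higher, median 1.30, camera adjusted p = 0.0614), but their sum stood at 7462 ± 2992 against 2748 ± 159 CPM without overlap. Eosinophil markers did not pass either (5 of 9 higher, median 1.93, camera adjusted p = 0.122), with their sum at 317.5 ± 42.7 against 62.6 ± 27.2 CPM. Cd163, a scavenger receptor of macrophages, rose by 6.0 ± 0.88, Ccr2, the receptor of inflammatory monocytes, by 3.51 ± 0.24, Xcr1, of cross-presenting dendritic cells, by 4.39 ± 0.47, and Cd74, the MHC class II chaperone, by 2.49 ± 0.19. Il1b rose from 1064 ± 163 to 3259 ± 356 CPM and Fos from 1121 ± 601 to 6202 ± 1230 CPM. T and NK cell markers did not pass (2 higher and 1 lower of 15, 1 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.461). Arg1 rose (log2 3.20 ± 1.14, adjusted p = 0.0304), but not without isotype replicate 1 (2.81), isotype replicate 3 (2.91) or anti-GCF replicate 2 (2.17). In all, 5309 genes rose and 4414 fell. Upper-quartile scaling moved the median of all genes by −0.13 and gave 4674 higher and 4953 lower.

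**Figure D3:**
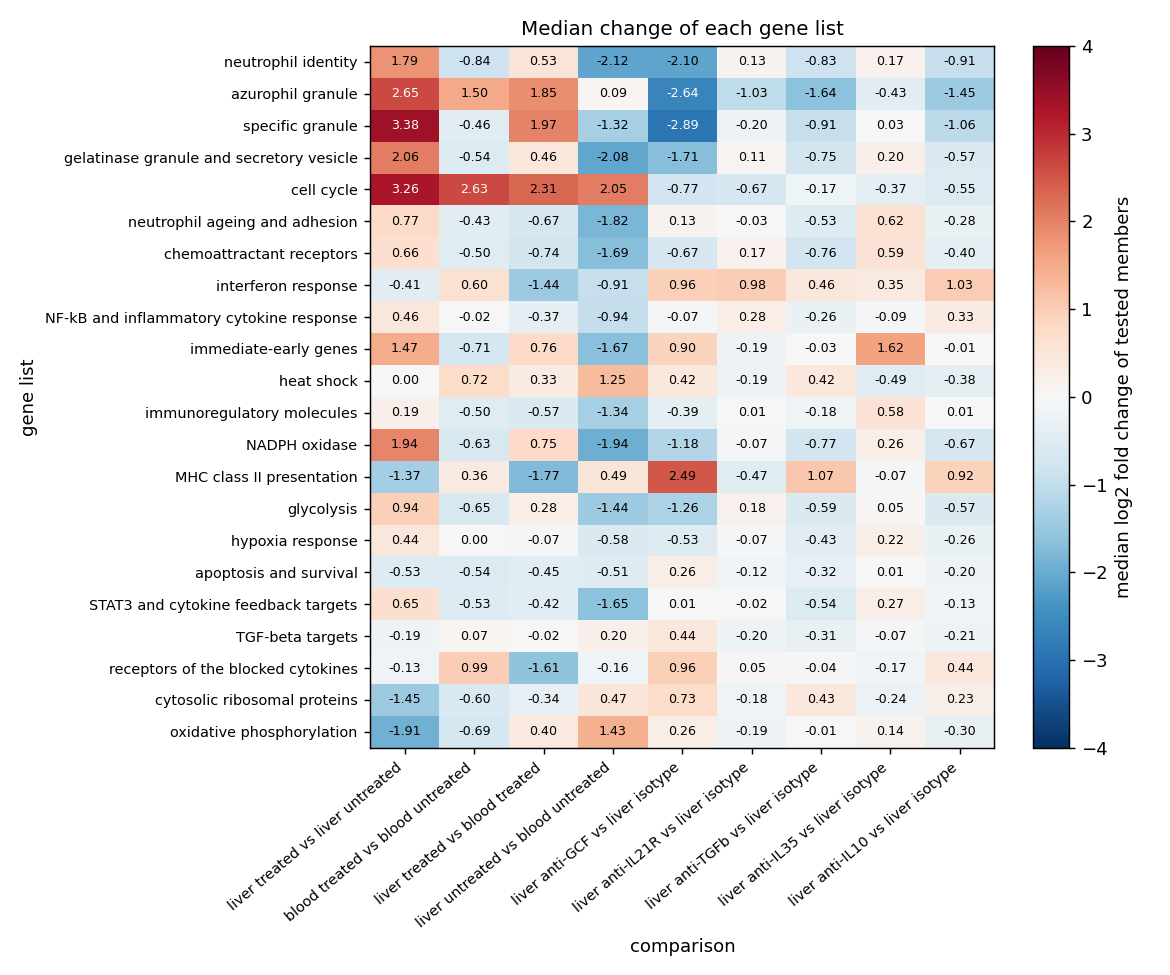
Median log2 fold change of each pathway and neutrophil gene list (rows) in 9 comparisons (columns), on a colour scale from lower to higher. Specific granule genes had a median of 3.38 in treated against untreated liver and −2.89 in anti-GCF against isotype.

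Anti-IL21R changed few genes. Some cell cycle and erythroid genes were lower, at levels of calprotectin and lactoferrin near those of isotype. Of 30 cell cycle genes 9 fell (17 adjusted over the list alone, median −0.67, camera adjusted p = 6.36e-09), among them Ube2c, an enzyme of mitotic exit, at 13.6 ± 0.74 against 27.4 ± 7.76 CPM (SD, n = 3 each, log2 −1.02 ± 0.19, adjusted p = 0.0274). Erythroid markers fell beside them in 7 of 10 (9 adjusted over the list alone, median −2.60, or −2.52 with genes at 0 set to their bound, 3.53e-07), and endothelial markers in 2 of 12 (11 adjusted over the list alone, median −3.50, 3.06e-06). The endothelial markers summed to 36.7, 414 and 204 CPM in isotype replicates 1, 2 and 3 and to 30.6 ± 3.1 CPM under anti-IL21R (n = 3). Azurophil granule genes fell in 2 of 10 (3 adjusted over the list alone, median −1.03, 0.0105), including Ctsg, the serine protease cathepsin G (−1.32 ± 0.32), with overlapping sums (676 ± 94.8 against 799 ± 98.7 CPM). Under an estimated correlation each adjusted p was 0.829. Of 36 interferon response genes 1 rose, Iigp1 (4 adjusted over the list alone, median 0.98, camera adjusted p = 3.06e-06, and adjusted p = 0.829 with an estimated correlation), by 2.03 ± 0.36. The summed level of this list was 2208, 12912 and 3408 CPM in anti-IL21R replicates 1, 2 and 3, against 1633 ± 131 CPM under isotype (n = 3). Cd274 rose from 128 ± 13.5 to 373 ± 144 CPM (log2 1.54 ± 0.35, adjusted p = 0.0447), Traf1, a TNF receptor adaptor, by 1.19 ± 0.19, Nlrc5, the activator of MHC class I genes, by 2.23 ± 0.45, and Hdc, histidine decarboxylase, by 0.82 ± 0.20. S100a8 stood at 39330 ± 6140 against 38650 ± 6050 CPM (adjusted p = 0.971) and Ltf at 21990 ± 6880 against 21030 ± 4810 CPM (adjusted p = 0.952). In all, 181 genes rose and 194 fell, and each gene called here lost its call without isotype replicate 2 or 3 or anti-IL21R replicate 2 or 3 (over all settings run, Ube2c ranged from −1.18 to −0.77 and Cd274 from 1.19 to 1.75). The total of 375 was 2123, 3, 7, 188, 2 and 2 without isotype replicates 1, 2 and 3 and anti-IL21R replicates 1, 2 and 3, 1578 in DESeq2, 222 without a filter and 22 in a fit of these groups alone.

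Under anti-TGFb, T and NK cell markers were higher and neutrophil identity genes lower. Gzma stood at 103 ± 1.31 CPM (SD, n = 2) against 9.38 ± 3.08 CPM (n = 3), a log2 fold change of 3.46 ± 0.28 (SE, adjusted p = 1.03e-05), and Ncr1, an activating receptor of NK cells, rose by 3.52 ± 0.32. Of 15 T and NK cell markers 14 rose (median 2.70, camera adjusted p = 2.09e-08, and adjusted p = 0.829 with an estimated correlation), with their sum at 993 ± 33.0 against 376 ± 65.8 CPM. Saa1 and Saa2, acute-phase genes with near-identical sequences, stood at 16.2 ± 2.84 against 0.14 ± 0.10 CPM and at 33.8 ± 4.46 against 0.09 ± 0.04 CPM, while Saa3 did not pass (58.1 ± 42.5 against 38.9 ± 16.8 CPM, adjusted p = 0.775). Iigp1 rose by 5.07 ± 0.41 and Gbp5 by 3.00 ± 0.53, while the interferon response list did not pass (11 higher and 1 lower of 36, camera adjusted p = 0.0614). Hepatocyte markers rose in 7 of 17 (10 adjusted over the list alone, median 1.58, camera adjusted p = 5.22e-05), and MHC class II genes in 8 of 13 with 1 lower (9 and 1 adjusted over the list alone, median 1.07, 0.00345). Each adjusted p with an estimated correlation was 0.829. Dendritic cell markers summed to 496.7 ± 88.2 against 198.4 ± 29.5 CPM, without overlap. Monocyte markers summed to 1173.7 ± 280.6 against 584.2 ± 247.4 CPM, also without overlap. Sums of macrophage (347.9 ± 77.3 against 449.1 ± 169.1 CPM) and B and plasma cell markers (2366 ± 239.4 against 2747.5 ± 159.2 CPM) were not higher.

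Identity genes fell under anti-TGFb in 7 of 20 (12 adjusted over the list alone, median −0.83, camera adjusted p = 3.06e-06), azurophil genes in 6 of 10 with 1 higher (7 and 1 adjusted over the list alone, −1.64, 0.0177) and specific granule genes in 3 of 14 (−0.91, 0.000752). Under an estimated correlation the adjusted p were 0.829. Il1r2 fell by 1.69 on the log2 scale (SE 0.31). Elane (−2.59 ± 0.72, adjusted p = 0.0215) passed in the full set but not without anti-TGFb replicate 1 (−2.15) or replicate 2 (−3.20). Camp stood at 4645 ± 394 against 10180 ± 2320 CPM (adjusted p = 0.0887) and S100a8 at 19810 ± 1420 against 38650 ± 6050 CPM (adjusted p = 0.0605). The TGF-beta target list did not pass (1 higher and 3 lower of 15, median −0.31, camera adjusted p = 0.162), with Pmepa1, a feedback inhibitor of the pathway, higher by 1.66 ± 0.30. Klf10, an early target, was lower (−1.60 ± 0.37), though not past the threshold without anti-TGFb replicate 1 (−1.42). In all, 2947 genes rose and 1688 fell. The total of 4635 was 2605 at a log2 fold change of at least 1 (2187 higher and 418 lower), 3027 without isotype replicate 2, and 2030 and 1580 without anti-TGFb replicates 1 and 2 (1747 and 1350 higher, 283 and 230 lower), so the balance of directions depends on these choices.

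Under anti-IL35, immediate-early genes were higher, while the 3 lists of granule genes did not pass. Jun stood at 5335 ± 298 CPM (SD, n = 2) against 675 ± 102 CPM (n = 3), a log2 fold change of 2.98 ± 0.34 (SE, adjusted p = 0.000616). Fos rose by 3.40 ± 0.48, Dusp1, a phosphatase of MAP kinases, by 2.94 ± 0.40, and Rhob, a small GTPase, by 2.73 ± 0.27. Of 19 immediate-early genes 12 rose and 2 fell (13 and 3 adjusted over the list alone, median 1.62, camera adjusted p = 1.39e-05, and adjusted p = 0.829 with an estimated correlation). Dusp4, another such phosphatase, fell by 2.88 on the log2 scale (SE 0.27), Cdk18, a cyclin-dependent kinase, fell by 3.31 (SE 0.44), Traf1 fell by 1.74 (SE 0.23) and Tgif1, a repressor in TGF-beta signalling, fell by 2.22 (SE 0.20). Ribosomal protein genes fell in 10 of 82 with 0 higher in edgeR (14 with 1 higher adjusted over the list alone, median −0.24, camera adjusted p = 0.000165, and adjusted p = 0.831 with an estimated correlation, sums overlapping at 3563 ± 85.9 against 3752 ± 782 CPM), and adhesion genes rose in 3 of 14 (median 0.62, camera adjusted p = 0.00758, and adjusted p = 0.829 with an estimated correlation). Of 14 specific granule genes 0 passed in edgeR (median 0.03, −0.06 with upper-quartile scaling and −0.01 in limma-voom, camera direction down with adjusted p = 0.713), and the azurophil (1 lower of 10, camera adjusted p = 0.166) and gelatinase granule lists (1 higher of 13, 2 adjusted over the list alone, 0.193) did not pass, with Ltf at 23230 ± 15500 against 21030 ± 4810 CPM (adjusted p = 0.896). Macrophage markers summed to 329 CPM in anti-IL35 replicate 1 and 2726 CPM in replicate 2. Cxcr2 (log2 1.38 ± 0.27) and Il1b (1.99 ± 0.49) passed in the full set but not without anti-IL35 replicate 2 (0.66 and 0.09). In all, 809 genes rose and 759 fell (734 and 782 with RLE scaling, 475 and 902 with upper-quartile scaling). A fit of these groups alone called 0 genes in edgeR (2119 at an unadjusted p under 0.05), 0 in limma-voom and 578 in DESeq2. The total of 1568 was 199, 3558, 906 and 566 without anti-IL35 replicate 2, anti-IL35 replicate 1, isotype replicate 1 and isotype replicate 3, and 761 at a log2 fold change of at least 1.

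Under anti-IL10, T and NK cell markers and interferon response genes were higher and neutrophil identity and specific granule genes lower. Gzmb, granzyme B, stood at 84.9 ± 0.10 CPM (SD, n = 2) against 4.88 ± 0.25 CPM (n = 3), a log2 fold change of 4.12 ± 0.18 (SE, adjusted p = 3.74e-08). T and NK cell markers rose in 12 of 15 with 1 lower (14 and 1 adjusted over the list alone, median 2.28, camera adjusted p = 1.58e-08, and adjusted p = 0.829 with an estimated correlation), with their sum at 782 ± 52.8 against 376 ± 65.8 CPM. Saa1 rose by 7.10 ± 0.90 and Saa2 by 8.11 ± 0.94, while Saa3 did not pass (43.8 ± 35.8 against 38.9 ± 16.8 CPM, adjusted p = 0.947). Hepatocyte markers were also higher by their sum, at 440 ± 5 against 229.9 ± 166.1 CPM without overlap. Among them Alb overlapped, at 155 and 165 CPM against 48.3, 52.9 and 184 CPM. Of 36 interferon response genes 12 rose and 0 fell in edgeR (median 1.03, camera adjusted p = 6.41e-05, and adjusted p = 0.834 with an estimated correlation), with Iigp1 higher by 3.48 ± 0.39. Il6, an inflammatory cytokine gene, rose from 2.37 ± 0.92 to 18.2 ± 2.09 CPM, and Cish, a cytokine feedback inhibitor, by 2.67 ± 0.24. MHC class II genes rose in 8 of 13 with 1 lower (9 and 1 adjusted over the list alone, median 0.92, camera adjusted p = 0.00317), and basophil and mast cell markers in 4 of 8 (5 adjusted over the list alone, median 1.68, 0.0262). Under an estimated correlation each adjusted p was 0.829. Dendritic cell markers summed to 320.8 ± 64.6 against 198.4 ± 29.5 CPM, without overlap. B and plasma cell markers summed to 4049.3 ± 891.3 against 2747.5 ± 159.2 CPM, also without overlap. Sums of monocyte (1026.5 ± 325.6 against 584.2 ± 247.4 CPM) and macrophage markers (438.6 ± 104.3 against 449.1 ± 169.1 CPM) overlapped.

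Neutrophil identity genes fell under anti-IL10 in 8 of 20 (10 adjusted over the list alone, median −0.91, camera adjusted p = 5.85e-06), specific granule genes in 6 of 14 (9 adjusted over the list alone, −1.06, 3.06e-06), azurophil genes in 6 of 10 with 1 higher (7 and 2 adjusted over the list alone, −1.45, 0.0128, sums overlapping at 635 ± 140 against 799 ± 98.7 CPM) and cell cycle genes in 8 of 30 (10 adjusted over the list alone, −0.55, 0.000264). Erythroid markers fell beside them in 5 of 10 (9 adjusted over the list alone, −2.58, 2.83e-05). Each adjusted p with an estimated correlation was 0.829. Camp stood at 3240 ± 2260 against 10180 ± 2320 CPM (log2 −1.65 ± 0.48, adjusted p = 0.0332) and S100a8 at 14840 ± 8360 against 38650 ± 6050 CPM (−1.38 ± 0.37, adjusted p = 0.0227). Both calls ended without anti-IL10 replicate 1 (−1.07 and −0.90), isotype replicate 2 (−1.58 and −1.34) or isotype replicate 3 (−1.53 and −1.29). Cd274 rose from 128 ± 13.5 to 333 ± 90.5 CPM (log2 1.38 ± 0.37, adjusted p = 0.0262), but not without the same libraries, with values from 1.07 to 1.34. Il10 itself stood at 6.31 ± 3.00 against 4.27 ± 0.73 CPM (adjusted p = 0.583). In all, 1787 genes rose and 1174 fell. The total of 2961 was 288 without anti-IL10 replicate 1 (266 higher and 22 lower), 1479 and 1888 without isotype replicates 2 and 3, 1052 in a fit of these groups alone (859 higher and 193 lower) and 1743 at a log2 fold change of at least 1.

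The genes that separated treated from untreated liver were followed under each antibody. Of the 4649 genes higher in treated liver, 4260 were tested in the antibody table, and of the 6071 lower, 5118. Under anti-GCF the up set had a median log2 fold change of −0.62 and the down set 0.79, under anti-TGFb −0.41 and 0.52, and under anti-IL10 −0.30 and 0.38. Adjusted p with an estimated correlation were 0.014 and 0.00788 for anti-GCF, 0.014 and 0.00788 for anti-TGFb, and 0.0211 and 0.0147 for anti-IL10. With a signature from treated liver against treated blood instead, chosen after seeing the data, these adjusted p ranged from 0.278 to 0.602, with medians in the same directions (−0.79 and 1.10 for anti-GCF, −0.37 and 0.61 for anti-TGFb, −0.45 and 0.69 for anti-IL10). With the 100 genes of smallest p-value in each direction they ranged from 0.135 to 0.566, again with medians in the same directions (−0.99 and 0.65, −0.41 and 2.27, −0.31 and 1.29). Under anti-IL21R the medians were 0.10 and −0.16 (adjusted p = 0.314 and 0.126 with an estimated correlation), and under anti-IL35 they were 0.10 and 0.07 (0.685 and 0.804). Hepatocyte and ribosomal protein genes are part of the down set, and most neutrophil identity genes are part of the up set. Identity genes summed to 154481 ± 13722 CPM under isotype, 26212 ± 3493 under anti-GCF, 83873 ± 4571 under anti-TGFb and 70828 ± 34861 under anti-IL10. Their sums were 165223 ± 24570 CPM under anti-IL21R and 162734 ± 46445 under anti-IL35. The medians of these sets thus do not separate a change in neutrophil content from a change within neutrophils.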

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

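All tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the libraries. The treatment effect differed between liver and blood by the test of the difference itself in 9143 genes. Hepatocyte markers summed to 17336 ± 3720 CPM in untreated and 279 ± 17.6 CPM in treated liver. Such a difference in cell content, far larger in liver than in blood, does not cancel in the interaction, and its part in these genes was not tested. Among named genes the liver effect minus the blood effect (log2) was 5.23 for Camp, 5.18 for Ltf, 3.72 for S100a8, 4.58 for G0s2, 2.81 for Mmp9, 6.31 for Osm, 6.75 for Has2, 7.25 for Fosl1, 4.83 for Hvcn1, 3.54 for Klf2, 3.03 for Vegfa and 1.16 for Cxcr2. It was 2.3 for Cxcr4, a call that ended without any of 7 of the 9 libraries (over all settings run, values from 1.758 to 2.913). It was −5.41 for Arg1, −7.68 for C1qc, −7.06 for Gzma, −8.17 for Iigp1 and −5.7 for Hspd1.

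Specific granule genes were higher in treated than in untreated liver. Less RNA of other cells would raise all neutrophil genes alike, but the mean log2 level of granule genes rose by 1.38 more than that of identity genes. This difference of means went from −1.1 to 0.28 in liver. It also rose in blood, from −2.18 ± 0.32 in untreated (SD, n = 3) to −1.57 in treated libraries (n = 2). A shift added to all treated libraries would cancel in the interaction, where the granule genes had a median of 3.37. Each test took its explanation alone, and less RNA of other cells together with such a shift was not tested. A batch that acts on liver libraries alone was not tested, and it cannot be told apart from treatment. More granule-rich or younger neutrophils in treated liver may account for the pattern, a hypothesis found on these data and not tested. The azurophil granule and cell cycle lists, which rose in treated liver, did not pass in the interaction.

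Neutrophil genes were lower under anti-GCF than under isotype. A lower share of neutrophils with all other cells rising alike is argued against by a gap of 3.99 between the median log2 fold changes of macrophage markers and of T and NK markers. That gap does not bear on a lower share with an uneven mix of other cells, which was not tested and stays open. Sums of monocyte (5521 ± 1372 against 584 ± 247 CPM), dendritic cell and B and plasma cell markers were also higher. Those of T and NK, cholangiocyte, and basophil and mast cell markers were lower. Dilution by macrophage RNA as the whole cause cannot be told apart from a change within neutrophils, although 13 of 20 identity genes had a 95% interval that left out the list median (Cxcr2 −0.03 and Il1r2 −3.77). Macrophages express some of these genes, and the bound for this test was rewritten after the value was seen. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many as 9723 genes, and the highest other gave 0 in edgeR (184 to 683 genes at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05.

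For anti-IL21R the real split gave 375 genes (1 of 10 splits) and the highest other 113, from the split that put isotype replicate 1 with anti-IL21R replicates 2 and 3, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 3897 genes and that other split 3818, so by this count they hardly differed.

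Cell cycle genes were higher in treated liver than in treated blood. Proliferating T or NK cells are argued against by their markers, with a median log2 fold change of −4.97, although 1 of 15, Cd3d, was higher (log2 2.84 ± 0.28). B and plasma cells were not weighed and stay open, since their markers had a median of −2.84 but Ighm, the IgM heavy chain, stood at 331 ± 38.3 against 102 ± 13.2 CPM. Erythroid precursors stay open, since erythroid markers had a median of 1.5 with 3 of 10 called. Immature granulocytes may account for the pattern, since the azurophil granule genes, made early in granulocyte development, had a median of 1.85, a hypothesis. Cell cycle genes were also higher in liver without therapy, with sums of 129.8 ± 25.9 CPM in untreated liver and 29.5 ± 4.2 CPM in untreated blood. There the azurophil genes had a median of 0.09 (−0.13 with upper-quartile scaling), so the lists did not rise together in untreated mice.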

How the results depend on the processing

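Counts of changed genes stayed within 1.5 times under every alternative run for treated against untreated liver (8345 to 9704 without 1 library), untreated liver against blood (9120 to 11189), the interaction (7153 to 9991) and anti-GCF (8519 to 8928). For treated against untreated blood, 5620 became 3442 with a log2 fold change of at least 1 and 1723 to 7201 without 1 library. For treated liver against treated blood, 3568 became 8188 with only the groups compared and 1467 to 1611 without 1 library. For anti-IL21R, 375 became 1578 in DESeq2, 222 without a filter, 22 with only the groups compared, 42 without the anti-GCF libraries, 196 with a log2 fold change of at least 1, and 2 to 2123 without 1 library. For anti-TGFb, 4635 became 2605 with a log2 fold change of at least 1 and 1580 to 4322 without 1 library. For anti-IL35, 1568 became 0 in edgeR with only the groups compared (2119 at an unadjusted p under 0.05, 578 in DESeq2 and 0 in limma-voom), 709 without the anti-GCF libraries, 761 with a log2 fold change of at least 1, and 199 to 3558 without 1 library. For anti-IL10, 2961 became 1052 with only the groups compared, 1743 with a log2 fold change of at least 1 and 288 to 3309 without 1 library. A fold threshold lowers such counts by construction, and otherwise the cause was not tested. The share of calls that were higher moved from 48.3% to 58.9% (RLE), 33.3% (upper-quartile), 58.6% (DESeq2) and 65.2% (limma-voom) for anti-IL21R, from 51.6% to 34.5% (upper-quartile) for anti-IL35 and from 60.4% to 49.1% (DESeq2) for anti-IL10. Of 146 list calls 0 remained with an estimated correlation. Socs3 under anti-IL35 turned to −0.102 without anti-IL35 replicate 2 and was 3.082 without replicate 1. The signature under anti-IL21R had medians of 0.099 and −0.157 that did not pass with an estimated correlation, 0.254 and −0.129 with 100 genes (adjusted p = 0.351 and 0.857 with an estimated correlation), and −0.072 (reversed) and −0.13 from treated liver against treated blood, which also reversed the up set under anti-IL35 to −0.111. That up set under anti-IL35 passed with the preset correlation (camera adjusted p = 0.0393) but not with the estimated one (0.795). With 100 genes the medians under anti-IL35 also changed sign, to −0.064 and −0.199, and neither of these sets passed. The replicate numbers are not stated to pair the libraries, and correlations between same-numbered libraries ran from −0.244 to 0.287. For anti-GCF, 3 of 3 libraries correlated best with the isotype library of their own number, and for anti-IL21R 0 of 3 did. A replicate block by title or library-name numbers gave 59 and 62 genes for anti-IL21R and 663 and 883 for anti-IL35.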

Other observations

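No test of an explanation was run in this part, and the comparisons in it were chosen after the result was seen. The responses to anti-TGFb and anti-IL10 overlapped. They shared 1550 of the genes called higher (313 if independent) and 828 of those called lower (118). Their log2 fold changes had a correlation of 0.827 and a covariance of 0.719. Simulated tables without any effect that share the 3 isotype libraries gave 0.405 and 0.075. A correlation of noise alone cannot be set against one that holds effects, so the covariances are the closer comparison. Genes do not vary independently, and the shared controls account for part of the overlap. The direct comparison of these antibodies called 0 genes in edgeR (1373 at an unadjusted p under 0.05), 0 in limma-voom and 140 in DESeq2. Saa2, a serum amyloid gene, stood at 30.6 and 36.9 CPM under anti-TGFb, 26.1 and 25.1 under anti-IL10 and 3.19 to 10.9 under anti-IL21R, and at 17.9 and 35.9 in untreated liver. Car3, a carbonic anhydrase abundant in liver and muscle, stood at 239 and 299 CPM under anti-TGFb and at 3134 and 4665 CPM in untreated liver. Hepatocyte markers summed to 671.6 ± 84.5 CPM under anti-TGFb and 440 ± 5 CPM under anti-IL10, against 229.9 ± 166.1 CPM under isotype.

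Sex-linked genes differed between the tables. Xist is expressed from the inactive X chromosome of females. In the 9-library table it ranged from 4.53 to 11.1 CPM in untreated and from 20.9 to 54.1 CPM in treated libraries. It thus separated treated from untreated libraries, which also fall into separate ranges of library numbers. Xist reached at most 0.149 CPM in the antibody table, where Ddx3y, a Y-linked gene, ranged from 80 to 412 CPM. The 9-library table held no values of Ddx3y. Alb ranged from 9.08 to 16.3 CPM in untreated blood and stood at 0.718 and 0.082 in treated blood. Ctrb1, a pancreatic enzyme precursor, stood at 29.7, 1.17 and 10.9 CPM in anti-GCF replicates 1, 2 and 3 and at 12.7 in anti-IL35 replicate 2, and Pnliprp1, a pancreatic lipase-related gene, at 28.7, 0.352, 5.45 and 3.99 CPM in the same libraries. Rn7sk, a small nuclear RNA, ranged from 23.7 to 28 CPM in untreated blood and stood at 4.66 and 3.05 in treated blood. In liver it hardly differed, at 10.4 and 8.4 CPM in untreated and 9.88 and 8.78 CPM in treated libraries.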
